A study of Drosophila melanogaster with 18 samples.

How the data were processed

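Per the labels, RNA from embryos collected over 0 to 3 h was hybridised to single-colour arrays, 18 samples in 6 groups of 3 biological replicates. The dye was Cy5 on 3 of 3 anti-Staufen arrays, 0 of 3 control antibody arrays, 1 of 3 wild-type total RNA arrays, 2 of 3 GFP-Staufen total RNA arrays, 2 of 3 anti-GFP arrays and 1 of 3 anti-FLAG arrays, and Cy3 on the others. The authors deposited log2 values made with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes; the log2 base was read from the values, which end at 16.0. The software version and which arrays were normalized together are not given in the sources used here. The array distributions differ between total RNA and RIPs and between experiments, so values set across these sets carry a scaling that the table does not settle.

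Of 17130 rows, 507 held no value and 16623 were tested, with no filter on signal. No array shared more than 14.3% of its values with another, so none was counted as a duplicate. Exact ties between replicates do occur, such as FBtr0075133 at 6.43 on all 3 GFP-Staufen total RNA arrays (SD 0). Such ties lower the replicate spread that the fit uses, and their effect on the calls was not tested. Groups and replicate numbers came from the labels. Each array column belonged to a sample.

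The rows are FlyBase transcript identifiers. The reference gene table (Release 6 plus ISO1 MT) holds such identifiers only among the synonyms of some genes: 46 transcripts on the array matched, 17 to 1 gene and 29 to several. The 17 are given their symbol and all others remain identifiers; no coordinate was used. For that reason the 26 gene lists fixed before the data were examined were not tested, since 1 of them held a transcript with a symbol, and bcd, osk, pros, nos, stau, cn and w, which were to be reported throughout, are not analysed here. The 3′ UTR lengths of the shared transcripts were not analysed either, for want of a reference annotation.

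Group means were fitted to all 18 arrays in limma 3.58.1 (R 4.3.3), with 12 residual degrees of freedom and no covariate, and contrasts were tested two-sided with lmFit and eBayes. Benjamini-Hochberg adjustment ran over all transcripts, with a call at an adjusted p threshold of 0.05. The difference between the experiments was the contrast of the anti-Staufen enrichment minus the anti-GFP enrichment. Standard errors are limma's moderated ones. Overlap was tested with Fisher's exact test, and a set of transcripts was tested in the other experiment with limma's camera at a preset correlation of 0.01 and again with an estimated one.

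Named transcripts were chosen by a rule written before the data were examined: the largest changes among calls in which all 3 arrays of a group lie beyond all 3 of the other, up to 8 higher and 4 lower for a RIP against its control RIP and up to 4 of each elsewhere. As few rows have a symbol, the rule was applied to those with one, and for a RIP against its control RIP the 2 highest and 2 lowest without a symbol are given by identifier. Dyrk3 in the anti-Staufen comparison was added after its value was seen.

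Replicate numbers were taken to pair the samples within each experiment. The deviations of same-numbered arrays from their group means correlated at 0.15 to 0.64 across transcripts in all 18 such pairs of arrays. Differently numbered arrays of an experiment lay at -0.50 to 0.39, so the ranges overlap. Some GFP-Staufen arrays did not part numbers 1 and 2, though others did. Anti-GFP RIP 2 correlated at 0.39 with anti-FLAG control RIP 1 and at 0.32 with anti-FLAG control RIP 2. Per the labels the GFP-Staufen extract was divided between the RIPs and the input. Between wild-type and GFP-Staufen total RNA the values were -0.01, 0.29 and 0.34. Same-numbered arrays of different experiments correlated at a median of 0.26, and differently numbered ones at -0.23. The negative value is no baseline. Deviations within a group cancel out by construction, so positive same-numbered values force negative ones elsewhere. The correlations alone therefore do not separate pairing within an experiment from a likeness of equal numbers across both. A fit with the number as a block was an alternative.

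The alternatives fixed before the data were examined were quantile normalization of all arrays or within experiments, median centring, cyclic loess, leaving out the dimmest 50% or 25% of transcripts, fits to only the groups or the 9 arrays of an experiment, array weights, a trended robust eBayes, dye as a term, the replicate block with and without dye, stricter thresholds, a plain equal-variance test, and leaving out each array. The fits were tested on simulated data with 200 changed transcripts among 16623 and noise drawn independently for each value. Deviations shared by same-numbered arrays and effects of dye were not simulated, so the shares below hold for independent noise only. For anti-Staufen against control antibody RIP, 90% of simulated log2 increases of 2 and 32% of increases of 1 were recovered, with 5.11% of calls false. For anti-GFP against anti-FLAG the values were 86%, 40% and 2.92%. For the difference between the experiments 68% of increases of 2 and 10% of increases of 1 were recovered.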

Results

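Staufen is a double-stranded RNA-binding protein of the fly Drosophila melanogaster that is known to take part in placing and regulating maternal mRNAs in the egg and early embryo. RNA from embryos collected over 0 to 3 h was measured on 18 single-colour expression arrays in 6 groups of 3 biological replicates each. In wild-type embryos, endogenous Staufen was recovered with a synthetic antibody (anti-Staufen RIP, an RNA co-immunoprecipitation), beside a control synthetic antibody (control antibody RIP) and total RNA. In embryos carrying a GFP-Staufen transgene, the fusion protein was recovered with anti-GFP, beside an anti-FLAG control RIP and total RNA. The table gave a log2 value for 16623 transcripts, and the number of arrays limits the precision of each comparison. Replicate arrays correlated across transcripts at r = 0.964 to 0.995, with the lowest value in the anti-FLAG control RIP and the highest in the anti-GFP RIP.

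The arrays of the 6 groups did not share a value distribution. The array medians lay at 6.94 to 7.03 in wild-type total RNA, 5.90 to 6.03 in the anti-Staufen RIP, 5.86 to 6.01 in the control antibody RIP, 6.81 to 6.88 in GFP-Staufen total RNA, 7.42 to 7.46 in the anti-GFP RIP and 6.91 to 7.17 in the anti-FLAG control RIP. Each RIP was therefore set first against the control RIP of its own experiment, whose upper quartiles nearly coincided. Rows carry transcript identifiers, and 17 of them could be given a gene symbol.

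**Figure D1:**
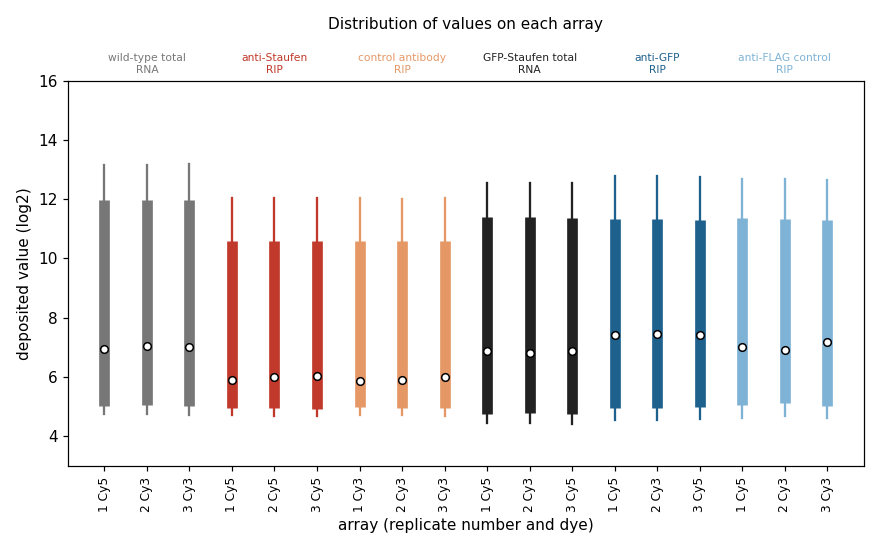
Each column is an array, labelled by replicate number and dye, and the vertical axis is the deposited log2 value; circles are medians, thick bars run from the 25th to the 75th percentile and thin lines from the 10th to the 90th percentile over 16623 transcripts. The RIP arrays of wild-type embryos have medians of 5.86 to 6.03, below those of wild-type total RNA at 6.94 to 7.03.

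The first comparison asked which RNAs were recovered with endogenous Staufen above the background of a control antibody. In the anti-Staufen RIP, 15 transcripts were higher and 9 were lower than in the control antibody RIP. The largest measured increase was in FBtr0075216, at 8.63 ± 0.90 (SD, n = 3) against 4.95 ± 0.20 (SD, n = 3), a log2 difference of 3.69 ± 0.33 (SE). Its control value lay at the 25th percentile of the control arrays, 4.94 to 4.97, at the dim end of the scale, which limits how well the size of the difference is known. FBtr0081664 was at 11.53 ± 0.88 (SD, n = 3) against 8.17 ± 0.14 (SD, n = 3), a difference of 3.36 ± 0.32 (SE). All 15 higher transcripts lay at least 2-fold above the control, 11 of them at least 4-fold, with a median log2 difference of 2.41. The decreases were led by FBtr0073221 at -5.43 ± 0.41 (SE) and FBtr0073224 at -4.80 ± 0.56 (SE). Both were also higher in the control antibody RIP than in wild-type total RNA, by 3.16 and 2.81 on the log2 scale. The adjusted p of these 4 transcripts was 4.2e-05, 7.0e-05, 9.0e-06 and 0.00046 in limma with Benjamini-Hochberg adjustment. None of the 17 transcripts with a symbol passed the test here, where limma gave 740 transcripts an unadjusted p under 0.05, below the 831 expected with no effect, and the plain equal-variance test called 0 of all transcripts. The number with an unadjusted limma p under 0.05 depended on the fit. It was 1425 with the replicate number as a block, 1327 after common quantile normalization of all arrays and 498 with dye as an added term.

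All 24 called transcripts had all 3 arrays of a group beyond all 3 of the other, as did 10.6% of all transcripts, where chance gives 10%. The calls rest on the spread estimated over all 6 groups: with only the 2 groups compared, 2 transcripts were called, both lower, whereas with the replicate number as a block 30 were higher and 21 lower. Every anti-Staufen array carried Cy5 and every control antibody array Cy3, and with dye as an added term 6 were higher and 5 lower; without anti-Staufen RIP replicate 3 the count was 14.

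The second comparison asked the same of GFP-Staufen. Against the anti-FLAG control RIP, 1859 transcripts were higher and 1436 lower in the anti-GFP RIP, of which 1167 and 716 differed at least 2-fold and 254 and 72 at least 4-fold. Dyrk3, a protein kinase of the DYRK family, was at 11.34 ± 0.39 (SD, n = 3) in the anti-GFP RIP and 6.63 ± 0.62 (SD, n = 3) in the anti-FLAG control RIP, a log2 difference of 4.71 ± 0.29 (SE) or 26.1-fold, with limma adjusted p = 1.1e-07. Of the other transcripts with a symbol, 2 were higher, NaPi-III, a sodium-dependent phosphate transporter, by 1.17 ± 0.26 (SE) and fend by 0.75 ± 0.18 (SE). With each array centred on its median NaPi-III was at 0.75 and still called, and fend at 0.33 and not called (limma adjusted p = 0.15); neither passed with only the groups compared (limma adjusted p = 0.051 and 0.054), nor NaPi-III, at 0.78, in the same-dye pairs alone (limma adjusted p = 0.053). HDAC3, a histone deacetylase, was lower, at 9.84 ± 0.11 (SD, n = 3) against 11.14 ± 0.25 (SD, n = 3), a difference of -1.30 ± 0.16 (SE) with limma adjusted p = 5.6e-05. The other 13 transcripts with a symbol did not pass; with the replicate number as a block CG16974, at 0.90, and kis, at -0.88, did (limma adjusted p = 0.0057 and 0.018). Without a symbol, the largest increases were in FBtr0084177 at 4.85 ± 0.32 (SE) and FBtr0075133 at 4.40 ± 0.37 (SE), both dim in the anti-FLAG control RIP at 5.50 ± 0.30 and 5.77 ± 0.80 (SD, n = 3). The largest decreases were in FBtr0075215 at -6.18 ± 0.56 (SE) and FBtr0075919 at -6.13 ± 0.59 (SE). Both sizes rest partly on anti-GFP RIP replicate 3, which lay far below the other replicates.

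FBtr0075215 and FBtr0075919 had a common profile over the RIPs. They were at 15.91 ± 0.06 and 15.92 ± 0.07 (SD, n = 3) in the anti-FLAG control RIP, close to the highest value of the table at 16.0, so the size of the difference from the anti-GFP RIP is limited by the top of the scale. They were also high in the control antibody RIP, at 15.27 ± 0.19 and 15.93 ± 0.05 (SD, n = 3), and in the anti-Staufen RIP, at 15.13 ± 0.43 and 15.82 ± 0.07 (SD, n = 3). In the anti-GFP RIP they were at 9.73 ± 1.67 and 9.79 ± 1.96 (SD, n = 3), below the 11.31 and 12.63 of GFP-Staufen total RNA. Anti-GFP RIP replicate 3 lay lowest, at 7.81 and 7.53. FBtr0075215 was at 10.62 and 10.76 on replicates 1 and 2, and FBtr0075919 at 10.88 and 10.96. The sizes of these differences thus rest partly on 1 array.

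In the anti-GFP comparison, 1757 of the higher and 1341 of the lower calls had all 3 arrays of a group beyond all 3 of the other, and 33.2% of all transcripts did, where chance gives 10%. With the replicate number as a block, 2896 were higher and 2465 lower; with only the 2 groups compared the count was 1358, and with each array centred on its median 930 were higher and 5498 lower.

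**Figure D2:**
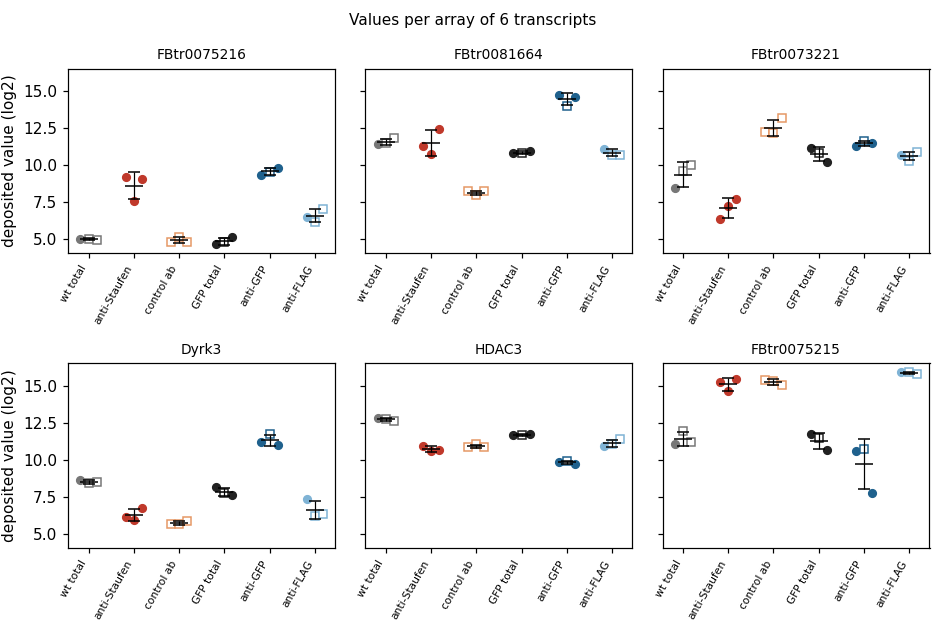
Deposited log2 value of 6 transcripts on each array, with groups along the horizontal axis; filled circles are Cy5 arrays, open squares Cy3 arrays, and bars are the mean ± SD of 3 arrays. Dyrk3 is at 11.34 in the anti-GFP RIP and 6.63 in the anti-FLAG control RIP. It is at 6.29 in the anti-Staufen RIP and 5.75 in the control antibody RIP. Values of different experiments are not on a settled common scale. FBtr0075216 and FBtr0081664 are higher in both Staufen RIPs than in their control RIPs.

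The recovered RNAs were then compared between the experiments, which share no arrays. All 15 transcripts higher in the anti-Staufen RIP were among the 1859 higher in the anti-GFP RIP, where 1.68 would be shared by independent lists (Fisher's exact test over transcripts, two-sided, p = 5.1e-15; transcripts are not independent). Their log2 differences were 1.51 to 3.69 in the anti-Staufen comparison and 1.92 to 3.76 in the anti-GFP comparison. In each of the 3 numbered pairs of both experiments, all 15 lay above the control RIP. The pair medians were 2.50, 1.69 and 3.39 for anti-Staufen and 2.39, 2.27 and 3.44 for anti-GFP. For anti-Staufen this sign adds nothing to the calls, as all arrays of the 15 lay above all control antibody arrays. FBtr0075216 was 3.00 ± 0.33 (SE) higher and FBtr0081664 3.61 ± 0.32 (SE) higher in the anti-GFP RIP than in the anti-FLAG control RIP. Against total RNA of their own embryos, all 15 were above 0 in the anti-GFP RIP and 14 were called higher, with a median of 2.77. In the anti-Staufen RIP 12 of the 15 were above 0 and 9 were called higher, with a median of 0.93 and a lowest value of -0.68; FBtr0081664 lay at -0.05. Common quantile normalization put that median at 1.93, with all 15 above 0 and 14 called higher. Of the 9 transcripts lower in the anti-Staufen RIP, 0 were called lower in the anti-GFP RIP by limma and 1 was called higher, with differences from -0.65 to 0.86; independent lists would share 0.78 lower calls, and 5513 transcripts had an unadjusted p under 0.05 in the anti-GFP comparison. With the replicate number as a block, 5 transcripts were lower in both, where independent lists would share 3.11.

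Over all transcripts the log2 differences of the comparisons correlated weakly, at Pearson's r = 0.18 and Spearman's rho = 0.10 across 16623 transcripts, which are not independent replicates. Against the anti-GFP pairs labelled with the same dye, numbers 1 and 2, r was 0.12 and 0.13. Against pair 3, whose dyes differ as in the anti-Staufen comparison, it was 0.23. Number 3 arrays also deviated together across the experiments, as given below, so dye and number cannot be told apart in pair 3. With dye as an added term r was 0.15. With the replicate number as a block, 28 transcripts were higher in both, with dye as an added term 6, and with only the groups compared 0; the count was 8 without anti-Staufen RIP replicate 3, 9 without control antibody RIP replicate 3 and 32 without anti-FLAG control RIP replicate 3.

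**Figure D3:**
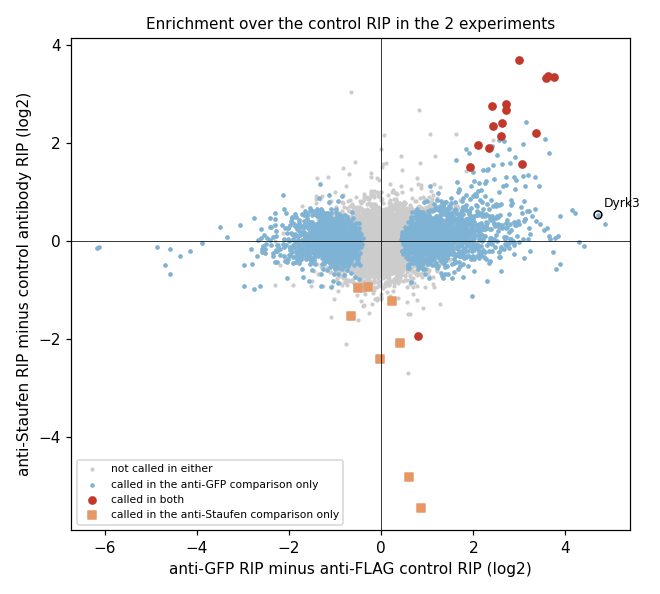
Each point is a transcript, with the log2 difference of the anti-GFP RIP from the anti-FLAG control RIP on the horizontal axis and that of the anti-Staufen RIP from the control antibody RIP on the vertical axis; colours give the calls at an adjusted p threshold of 0.05. The 15 transcripts higher in both lie at upper right, and Dyrk3, circled, lies at 4.71 and 0.54.

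The difference between the experiments was itself tested. The enrichment over the control RIP differed for 933 transcripts, larger with anti-Staufen for 394 and larger with anti-GFP for 539. Larger here means more positive. Of the 394, 384 were transcripts called lower in the anti-GFP RIP, and 0 were among the 15 called higher in both Staufen RIPs. The 1436 transcripts lower in the anti-GFP RIP had a median of -0.01 in the anti-Staufen comparison, with 0 called. The 394 are thus mostly decreases with anti-GFP, not increases with anti-Staufen. Dyrk3 was 0.54 ± 0.29 (SE) relative to the control in the anti-Staufen RIP, which did not pass the test, and the difference between the experiments was -4.17 ± 0.41 (SE) with limma adjusted p = 6.8e-05. HDAC3 differed by 1.12 ± 0.23 (SE) with limma adjusted p = 0.0096. It was at 10.76 in the anti-Staufen RIP and 10.93 in the control antibody RIP, so the positive value reflects its decrease in the anti-GFP comparison. Fatp1, at -0.96, did not pass (limma adjusted p = 0.082) but did with the replicate number as a block (limma adjusted p = 0.046). Of the 933 transcripts, 899 were also called in the anti-GFP comparison and 7 in the anti-Staufen comparison. The count was 2442 with the replicate number as a block, 605 with dye as an added term and 1410 without anti-FLAG control RIP replicate 3; it was 489 without anti-Staufen RIP replicate 2, 556 without its replicate 1, 553 and 606 without anti-GFP RIP replicates 2 and 1, and 592 and 614 without control antibody RIP replicates 2 and 1. Common quantile normalization turned the split to 359 larger with anti-Staufen and 302 larger with anti-GFP, and median centring to 1251 and 231.

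Enrichment over the starting RNA was examined in each experiment. In wild-type embryos the deposited values put 95 transcripts higher and 6895 lower in the anti-Staufen RIP than in total RNA. Of the 95, 54 were dim in total RNA, judged by the 25th percentile of its arrays (5.01 to 5.04). The median transcript was 0.54 lower on the log2 scale (median difference -0.54), a shift that common quantile normalization of all arrays moved to 0.06, giving 882 higher and 1222 lower. Of the calls made as deposited, 254 were then called in the opposite direction, among them fend, at -0.73 as deposited (limma adjusted p = 0.0039) and 0.60 after it (limma adjusted p = 0.047). Of the 13 transcripts with a symbol called as deposited, 5 changed sign, fend included. Cyclic loess gave 785 and 1338, quantile normalization within experiments 858 and 1152, and median centring 6800 and 2139. The transcript of kis, a chromatin remodeller, was -4.64 ± 0.43 (SE) relative to total RNA and -3.28 after common quantile normalization. That of mio, a component of the GATOR complex, was -2.81 ± 0.17 (SE) and -1.28 after it, with limma adjusted p = 0.00011 for both after it. Those of alpha-Spec, at -3.05 ± 0.53 (SE), and Dyrk3, at -2.25 ± 0.29 (SE), were called lower as deposited and not after common quantile normalization, at -1.34 and -0.73.

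The control antibody RIP had a like profile, with 127 transcripts higher and 7114 lower than in total RNA as deposited, and 948 higher and 1297 lower after common quantile normalization, which called 245 of the transcripts called as deposited in the opposite direction. Cyclic loess gave 795 and 1322, quantile normalization within experiments 868 and 1163, and median centring 7119 and 2053. The values of kis, at -4.64 ± 0.43 (SE), and mio, at -2.66 ± 0.17 (SE), were close to those of the anti-Staufen RIP. Dyrk3 was -2.79 ± 0.29 (SE) as deposited and -1.42 after common quantile normalization, where it still passed the test, and alpha-Spec was -3.29 ± 0.53 (SE) as deposited and -1.58 after it. These comparisons share their total RNA arrays, so their overlap was not tested. Of the 127 transcripts higher in the control antibody RIP as deposited, 98 were dim in total RNA by the same measure.

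In GFP-Staufen embryos, 3440 transcripts were higher and 1905 lower in the anti-GFP RIP than in total RNA. Of the 3440, 650 were dim in total RNA, judged by the 25th percentile of its arrays (4.74 to 4.78). Dyrk3 was higher by 3.46 ± 0.29 (SE) or 11.0-fold, NaPi-III by 1.33 ± 0.26 (SE), CG16974 by 1.24 ± 0.31 (SE) and fend by 0.76 ± 0.18 (SE). His4r, a gene of histone H4, was lower at -2.74 ± 0.33 (SE), HDAC3 at -1.87 ± 0.16 (SE) and mio at -1.27 ± 0.17 (SE). All of these kept their direction and call after common quantile normalization, with Dyrk3 at 3.64 and His4r at -3.12; centred on array medians, CG16974 and fend were no longer called. The split was 2027 higher and 1978 lower with common quantile normalization, 2473 and 2290 with cyclic loess, 2256 and 2164 with quantile normalization within experiments and 1058 and 5114 with median centring.

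The anti-FLAG control RIP showed 2129 transcripts higher and 1089 lower than GFP-Staufen total RNA. Of the 2129, 921 were dim in total RNA by the same measure. His4r was lower here too, at -2.63 ± 0.33 (SE), as were Dyrk3 at -1.24 ± 0.29 (SE), mio at -0.85 ± 0.17 (SE) and HDAC3 at -0.57 ± 0.16 (SE). Wdr24, another GATOR component, was higher by 0.73 ± 0.18 (SE) and Uba1, the ubiquitin-activating enzyme, by 0.47 ± 0.15 (SE). Wdr24 and Uba1 did not pass with median centring, at 0.56 and 0.30, nor Wdr24 without GFP-Staufen total RNA replicate 3, at 0.58. With only the groups compared, Dyrk3, Wdr24, Uba1 and HDAC3 did not pass (limma adjusted p = 0.078, 0.079, 0.11 and 0.11). With only the 9 arrays of the experiment, Wdr24, Uba1 and HDAC3 did not (limma adjusted p = 0.062, 0.094 and 0.069). HDAC3 and Uba1 did not pass without any single GFP-Staufen total RNA array or without anti-FLAG control RIP replicate 1 or 2, at -0.59 to -0.47 and 0.42 to 0.50. After common quantile normalization HDAC3 and Uba1 no longer passed, at -0.54 and 0.40, and 652 transcripts were higher and 913 lower. Cyclic loess gave 1109 and 1117, quantile normalization within experiments 980 and 1211, and median centring 932 and 1470; with the replicate number as a block 3525 were higher and 1942 lower, and the count was 2026 without GFP-Staufen total RNA replicate 2 and 2103 without anti-FLAG control RIP replicate 2.

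The starting RNA of the embryos was compared last. As deposited, 237 transcripts were higher and 4087 lower in GFP-Staufen total RNA than in wild-type total RNA, around a median difference of -0.40. HDAC3 was -1.04 ± 0.16 (SE), rdx -0.81 ± 0.22 (SE), NaPi-III -0.78 ± 0.26 (SE) and Wdr24 -0.75 ± 0.18 (SE), all called lower. Common quantile normalization brought the median difference to -0.01 and left none of the 4 called, at -0.49, -0.54, -0.23 and -0.15, with 355 transcripts higher and 289 lower. Cyclic loess gave 477 higher and 365 lower, quantile normalization within experiments 1425 and 245, and median centring 297 and 1933, so no direction is drawn for these genes. Leaving out wild-type total RNA replicate 1, GFP-Staufen total RNA replicate 1 or GFP-Staufen total RNA replicate 2 gave 2818, 2834 and 2817 calls.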

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

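The tests of dye, brightness, replicate number 3 and separate normalization below were chosen after the result was seen; the splits of the arrays were planned before.

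The enrichment over the control RIP differed between the experiments for 933 transcripts by a test of the difference itself, among them Dyrk3 at -4.17 (anti-Staufen minus anti-GFP, log2) and HDAC3 at 1.12. Of 100 drawn splits of the arrays within both experiments, 8 gave at least 933 calls, the real one included, and the highest other gave 1781. All 7 of these other splits kept the anti-GFP and anti-FLAG arrays in their real groups, as did 8 of the splits beside the real one, whereas the 91 that mixed them gave at most 3. The large counts therefore follow the grouping of the GFP-Staufen RIPs, a structure that mixing the wild-type arrays leaves in place, so this count does not decide about chance.

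The agreement of the 15 transcripts higher in both Staufen RIPs was weighed against 2 technical explanations. Dye separates the anti-Staufen from the control antibody arrays completely, but in the 2 anti-GFP pairs whose arrays carried the same dye the 15 transcripts still had a median log2 difference of 2.32, from 1.59 to 3.46, which dye alone would have brought near 0. Brightness was tested with 1000 random sets of 15 transcripts matched on mean signal: at most 8 of a set were higher in the anti-GFP RIP, on average 2.21, against 15 observed. The likeness of the number 3 arrays across the experiments was not weighed as a cause. The pair medians of the 15 were largest for number 3, at 3.39 for anti-Staufen and 3.44 for anti-GFP. In anti-GFP pairs 1 and 2 the lowest of the 15 were still at 1.70 and 1.49. A part of number 3 in the sizes stays open. Binding to beads or antibodies is accounted for only as far as the control RIPs share it. The 15 were chosen as higher than the control antibody RIP, so their 1.51 to 3.69 with anti-Staufen is no test of such binding. Above the anti-FLAG control RIP, a comparison on other arrays, all 15 lay by 1.92 to 3.76. What also stays open is binding that both recovering antibodies share and their controls lack, which was not tested. Beside it stands association with Staufen, which both antibodies were chosen to recover and which may be proposed only as a hypothesis.

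The excess of lower calls in GFP-Staufen total RNA, 4087 against 237, was set against separate normalization of the array sets. The dimmest 25% of transcripts had a median difference of -0.303, in the direction of the -0.40 of all transcripts, whereas the brightest 25% had -0.64, so the shift was not one constant over all levels. The shift of the dim transcripts is consistent with separate normalization as a source of part of the excess; a difference in RNA content between the genotypes is untested.

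For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05, and in each 1 split, the real one, reached the real count. The real count and the highest other were 24 and 0 for anti-Staufen against control antibody RIP, 3295 and 3 for anti-GFP against anti-FLAG, 6990 and 1 for anti-Staufen RIP against total RNA, 7241 and 0 for control antibody RIP against total RNA, 5345 and 2 for anti-GFP RIP against total RNA, 3218 and 2 for anti-FLAG RIP against total RNA, and 4324 and 0 between the total RNAs. Within each experiment, among the splits that, like the real one, part every numbered pair, the highest other was 0 throughout; the others keep 2 of the pairs together.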

How the results depend on the processing

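The replicate block took the numbers to pair arrays within experiments. It gave 51 calls for anti-Staufen against control antibody RIP (24 without it), 5361 for anti-GFP against anti-FLAG (3295) and 5467 for anti-FLAG RIP against total RNA (3218). It gave 2442 for the difference between the experiments (933) and 28 higher in both (15). In the other comparisons it moved the count by under 1.5 times. Among transcripts with a symbol it added CG16974 and kis in the anti-GFP comparison and Fatp1 in the difference and ended no call. For the total RNAs, which come from different embryos, it gave 6404 (4324). The block with dye gave 6, 5125, 1585 for the difference and 3 higher in both. Dye alone gave 11 for anti-Staufen, 605 for the difference and 6 in both; the standard errors grow when dye is fitted, and the 15 transcripts kept a median of 2.18 (2.41 without dye).

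Common quantile normalization gave 2104 calls for anti-Staufen RIP, 2245 for control antibody RIP and 1565 for anti-FLAG RIP against total RNA and 644 between the total RNAs; cyclic loess gave 2123 and 2117 for the first pair and 842 between the total RNAs; quantile normalization within experiments gave 2010, 2031 and 1670. Median centring gave 6428 for anti-GFP against anti-FLAG, 2230 between the total RNAs and 1482 for the difference. Common quantile normalization turned the sign of fend (-0.73 to 0.60, called both times), CG16974 (-1.08 to 0.28), His4r (-0.89 to 0.62), Fatp1 (-0.90 to 0.65) and Wdr24 (-0.60 to 0.39) in the anti-Staufen RIP against total RNA, and of 5 called transcripts with a symbol in the control antibody RIP. Of the values chosen by the naming rule, Wdr24 between the total RNAs turned, to 0.071 with quantile normalization within experiments. To these values were added Dyrk3 and HDAC3 in the difference, and Dyrk3 in the anti-Staufen comparison, which was not called. Counting each of them under each alternative, 817 stayed on their side of the threshold with their direction and 89 lost the call.

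Fits to only the groups compared, with fewer degrees of freedom, gave 2 for anti-Staufen, 1358 for anti-GFP against anti-FLAG, 899 for anti-FLAG RIP against total RNA, 579 for the difference and 0 in both; the 9 arrays of the experiment gave 1929 for anti-FLAG RIP against total RNA. The plain equal-variance test gave 0, 459, 483 for anti-FLAG RIP and 3436 for anti-GFP RIP against total RNA, 451 for the difference and 0 in both. Array weights gave 45, 5981, 8246 for anti-GFP RIP and 4836 for anti-FLAG RIP against total RNA, 6846 between the total RNAs, 2731 for the difference and 27 in both; the cause was not tested. A minimum log2 change of 1 gave 1883, 3190, 1505 and 1613 for anti-GFP against anti-FLAG, anti-GFP and anti-FLAG RIP against total RNA and the total RNAs, and an adjusted p threshold of 0.01 gave 1641, 3451, 1295 and 1899, with 282 for the difference; fewer calls follow from the stricter threshold. Leaving out the dimmest 50% gave 1424 for anti-FLAG RIP against total RNA, as fewer transcripts were tested. The same-dye anti-GFP pairs, chosen after seeing the data, gave 31 in both, and the lean of the anti-GFP set, 0.10, lost its call with an estimated correlation.

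Each array of the groups in a comparison was left out in turn, while arrays of other groups, which also enter the spread, were kept. This gave 14 to 24 calls for anti-Staufen and 2262 to 3802 for anti-GFP against anti-FLAG. For the wild-type RIPs against total RNA it gave 6231 to 6445 and 6461 to 6924. For anti-GFP RIP and anti-FLAG RIP against total RNA it gave 4257 to 4804 and 2026 to 3199. The total RNAs gave 2817 to 3618 and the difference 489 to 1410. Arrays of every RIP group were left out for the count in both, 8 to 32, and for the lean, 0.04 to 0.13. The 32, from a fit without an anti-FLAG array, are all anti-Staufen calls too, so 14 to 24 is not the full range for anti-Staufen. The cause of the other changes was not tested. The gene lists were not run, as 1 of the 26 held a transcript with a symbol, nor were the 3′ UTR lengths, for want of a reference annotation, nor single features per gene, as the table holds 1 value per transcript. Signal over background limits the dim transcripts.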

Other observations

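The tests in this part were chosen after the data were seen. Transcripts higher in the anti-GFP RIP leaned the same way in the anti-Staufen RIP. Of the 1859, 64.8% lay above 0 in the anti-Staufen comparison, against 47.6% of all other transcripts, with a median log2 difference of 0.10, which was 0.040 without anti-Staufen RIP replicate 3 (camera adjusted p = 0.032). The set was higher by camera (adjusted p over both sets 1.6e-06 with a preset correlation, adjusted p = 0.068 with an estimated correlation of 0.0445). In both comparisons the Staufen RIP holds more Cy5 arrays than its control RIP. With dye as an added term the median of the 1859 was 0.065. The set called higher by that fit had a median of 0.091 (camera adjusted p = 5.2e-05 with the preset correlation). The lean grew toward the top of the anti-GFP ranking: the 50 transcripts with the largest anti-GFP difference had a median of 0.51 in the anti-Staufen comparison with 43 above 0, the 200 largest a median of 0.36 with 160 above 0, and the 1000 largest 0.18 with 727 above 0. Without the 15 transcripts called higher in both, the other 1844 had a median of 0.09 with 64.5% above 0 (camera adjusted p = 7.9e-06 with the preset correlation, adjusted p = 0.089 with an estimated correlation), and the 50 largest a median of 0.41 with 42 above 0. The 1436 transcripts lower in the anti-GFP RIP had a median of -0.01 in the anti-Staufen comparison and 48.7% above 0 (adjusted p = 0.84 with the preset and 0.90 with an estimated correlation).

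The control RIPs of the experiments also shared RNAs, although they used different antibodies and share no arrays. After common quantile normalization, 113 transcripts were higher than total RNA in both control RIPs, where independent lists would share 37.2, and 276 were lower in both, where they would share 71.2 (Fisher's exact test over transcripts, two-sided, p = 3.5e-27 and 6.9e-96; transcripts are not independent). As deposited, 37 were higher in both, where 16.3 would be shared, and 955 lower in both, where 466 would be. The log2 differences correlated at Pearson's r = 0.25 and Spearman's rho = 0.24 across 16623 transcripts after common quantile normalization and at 0.38 and 0.36 as deposited.

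Arrays numbered 3 deviated from their group means together across both experiments, although the experiments used different embryos. The mean deviations of the number 3 arrays correlated at r = 0.59 across transcripts between the experiments, against 0.20 for number 1 and 0.44 for number 2. The last 2 values are not independent of the first. Deviations within a group cancel out, so a shared deviation of number 3 alone can make numbers 1 and 2 correlate. Of the transcripts that moved by over 0.5 on the log2 scale in both, 444 were up and 268 down in both and 15 went opposite ways. With dye fitted as a term the correlation was 0.608, which argues against dye. Among the dimmest 25% of transcripts it was 0.180 and among the brightest 25% 0.728, but the spread of the deviations was also smaller in the dim ones, 0.12 against 0.31 in the wild-type arrays, so a batch acting on every probe and a difference in the embryo collections cannot be told apart. Without all number 3 arrays, 25 transcripts were called in the anti-Staufen comparison, 4531 in the anti-GFP comparison and 16 higher in both; these held 15 of the 24, 2934 of the 3295 and 9 of the 15 called with all arrays.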
